A study of Homo sapiens with 32 samples.

How the data were processed

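Total RNA from 2 established inflammatory breast cancer cell lines, SUM149PT (SUM149 below) and SUM190PT (SUM190 below), was hybridised to 32 one-colour Agilent human miRNA arrays. Each line gave 4 groups of 4 arrays: vehicle, 10 nM 17β-estradiol, CG-1521, and both together, all for 48 h. CG-1521, which the series title calls a histone deacetylase inhibitor, was given at 7.5 µM to SUM149 and at 5 µM to SUM190. The labels describe the 4 arrays of a group as independent experiments, so each p-value measures the spread between these arrays. The media also differed between the lines.

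Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 10.1.1. The deposited scanner files hold linear intensity values per spot, with the local background already subtracted in the processed signal and no scaling between arrays. They also hold the median intensity of each spot and of its background, and a total gene signal in intensity units per miRNA, all as deposited. The authors' value table holds log2 values. It was checked against the scanner files: each value equalled log2 of the total gene signal, with values under 1 set to 1, minus a shift that varied within an array by at most 2.09e-06. The shift differed from log2 of the array's own 75th percentile by up to 0.02, so how that percentile was taken is not known in full.

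Values were computed from the processed signal with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Of 15739 spots per array, 15024 were miRNA spots. Control spots were left out, as were spots marked as outliers, which made up 5.82% to 8.15% of miRNA spots per array. The spots of a probe were averaged and the probes of a miRNA were summed. Of 851 human miRNAs, 483 had 2 probes, 308 had 4, 56 had 3 and 4 had 1. Each array was divided by its 75th percentile over the 19 human miRNAs detected on every array. Values were floored at log2 -7.25, the 1st percentile of the scaled signals of detected entries, and expressed as log2. Detection followed the Feature Extraction gene detection call. In all, 576 human miRNAs were detected on no array and 69.9% of the human values lay at the floor. The number of arrays and their brightness limit the precision.

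Tests used limma 3.58.1 in R 4.3.3, with group means, lmFit and eBayes without trend, two-sided, at an adjusted p under 0.05 by Benjamini-Hochberg with no fold minimum. A human miRNA was tested in a line if it was detected on all 4 arrays of at least 1 of its groups, which left 149 miRNAs in SUM149 and 107 in SUM190. A joint fit of both lines covered 160 miRNAs. All arrays of a fit, 16 for a line and 32 for both lines, shared a common estimate of the spread for each miRNA. The comparisons were estradiol, CG-1521 and the combination against vehicle, the combination against CG-1521, their interaction, and the estradiol effect averaged over both CG-1521 levels. The joint fit compared the vehicle arrays of the lines and tested the difference between the lines in the CG-1521 and estradiol responses. Array brightness and the number of detected miRNAs were compared by two-sided exact permutation tests with scipy 1.17.1. Overlap between the lines used a one-sided Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

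The miRNAs named were chosen by a rule written before the data were examined. It took up to 10 called miRNAs each way with the largest change whose groups did not overlap and which were detected on every array of the higher group. For interactions it took called miRNAs by size alone. It added up to 4 called members of each list by smallest adjusted p, or up to 2 by smallest p where none was called, and allowed the miR-200, let-7, miR-17-92, miR-34, miR-449, miR-221, miR-222 and miR-210 members throughout. Where a miRNA was undetected on all 4 arrays of the lower group, its fold is given as a lower bound. The bound sets each of those arrays to the higher of its own value and the lowest signal detected on that array. The report and the section on processing name other miRNAs only where they say so.

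Also before the data were examined, 27 lists were fixed: the miR-200, let-7, miR-23/27/24, miR-29, miR-30, miR-15/16, miR-34 with miR-449, miR-181, miR-125/99/100 and miR-221 with miR-222 families; miR-17-92 with its paralogous clusters, miR-183 with miR-96 and miR-182, and miR-302 with miR-371; the 14q32, C19MC and Xq27 clusters; ESR1-targeting, p53-responsive, epithelial and hypoxia-responsive miRNAs; blood-cell, neuronal, stromal, muscle and liver miRNAs; entries later reassigned to other RNAs; and high-numbered miRNAs of GC-rich sequence. The GC-rich list was drawn up from general knowledge. The GC content of its members was not measured, so its name is a label and not a measured property of each member. Of 265 listed names, 261 were on the array. Lists with at least 3 tested members were tested with camera at its preset correlation, and again with an estimated correlation. The arrays also carry 88 viral entries, which were left out of the tests.

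The replicate numbers were checked for pairing on residuals from the group means. In SUM190 all 24 pairs of arrays that share a number correlated above 0.1 (median 0.63, lowest 0.27), and 14 of 16 arrays correlated best with an array of their own number. In SUM149 9 of 24 pairs did (median 0.00) and 7 of 16 arrays. The labels do not say what a number shares, so the unpaired fit was kept and the fit with the number as a block is given beside it where the call differs. On every array the number was also the column of the slide. A shared column therefore cannot be told apart from a shared experiment.

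The limma fit was tested on simulated data, 20 times with 40 changed miRNAs each. The simulated values had independent normal residuals with the measured SD of each miRNA. They held no floor, scaling step, detection filter, dim array or correlation between arrays. The rates below therefore describe the fit alone and not the full processing of these data. For CG-1521 against vehicle in SUM149, with 149 miRNAs, it recovered 43.5% of changes of log2 1 and 79.0% of changes of log2 2, with 4.74% false calls and 97.8% of the right direction. For the same comparison in SUM190, with 107 miRNAs, it recovered 89.0% and 97.0%, with 3.64% false calls and 99.4% of the right direction.

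The alternatives were the 75th percentile over all human miRNAs, quantile normalization, the authors' value table, normexp background correction, the brightest probe, the total gene signal, a higher floor, no detection filter, only miRNAs detected on every array, the replicate block, a trended and robust prior, only the arrays of the groups compared, and leaving out each array. The scanner files lack the mean spot signal planned for normexp, so the median signals were used, with an offset of 50. All human miRNAs, quantile normalization and the authors' table served as scalings among these. A pair of scalings was added after the data were seen: the 75th percentile, and the median ratio to the mean profile, over the 59 miRNAs detected on the 31 arrays other than SUM149 vehicle replicate 2. Seed 1 was used throughout. No genome was needed and no coordinates are given.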

Results

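The series measured miRNA signals in SUM149 and SUM190 cells, which the labels describe as lacking the estrogen receptor and carrying mutant p53, after vehicle, 10 nM estradiol, CG-1521 or both. There were 8 groups of 4 arrays on 4 slides. In each line the vehicle and estradiol arrays shared a slide, and the arrays with CG-1521 shared another, so slide and CG-1521 could not be told apart, and estradiol coincided with the row of the slide. The replicate number coincided with the column. The lines were scanned on different days.

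The 75th percentile of the unscaled signal was 538 ± 341 (SD, n = 4) intensity units with vehicle in SUM149, ranging from 88.2 in replicate 2 to 872, and 158 ± 36.0 (n = 4) in SUM190. With CG-1521 it was 805 ± 482 and 184 ± 56.5. The number of human miRNAs detected with vehicle was 111.0 ± 34.7 in SUM149, with 59 in replicate 2. It was 176 ± 22.5 with CG-1521 and 158.5 ± 22.6 with the combination. In SUM190 it was 96.5 ± 9.40 with vehicle, 115.5 ± 7.85 with CG-1521 and 115.25 ± 1.26 with the combination. None of these 12 differences passed the exact permutation test after adjustment, for which the smallest possible p with 4 against 4 arrays was 0.0286. The SUM149 CG-1521 and combination groups and the SUM190 combination group reached that p for detected miRNAs, with an adjusted p of 0.114 each. The test ignored the replicate numbers, which pair the arrays in SUM190. There each CG-1521 and combination array had more detected miRNAs than the vehicle array of its number. Each SUM190 estradiol array had a lower 75th percentile than the vehicle array of its number. With estradiol the detected number was 143.75 ± 18.8 in SUM149 (exact adjusted p = 0.274) and 88 ± 6.98 in SUM190 (exact adjusted p = 0.386). Replicate arrays correlated at r = 0.89 to 0.99 across miRNAs within groups except SUM149 vehicle, where the lowest r was 0.62.

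**Figure D1:**
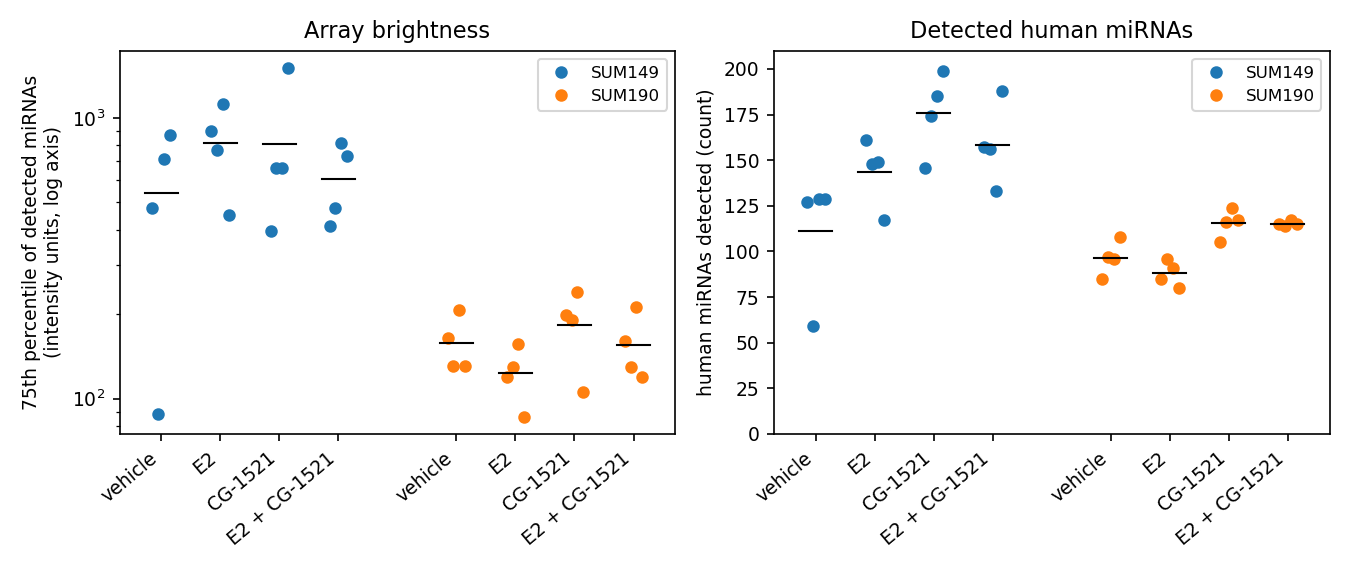
Unscaled 75th percentile of signal (intensity units, log axis) and number of detected human miRNAs per array in the 8 groups; points are arrays and lines are group means. SUM149 vehicle replicate 2 lies lowest of its group in both, with 88.2 units and 59 miRNAs.

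With CG-1521 in SUM149, the signals of miR-630, miR-638, miR-1207-5p, miR-663, miR-1225-5p and miR-1915 rose by log2 3.36 to 4.40, and the rise held its call and direction under every scaling tried. The largest rises were those of miR-630, by 4.40 ± 0.50 (SE, n = 4 and 4; limma adjusted p = 4.46e-06), and miR-638, by 4.20 ± 0.35, from -5.11 ± 0.55 (SD) to -0.91 ± 0.71. Without vehicle replicate 2 the rises of miR-1207-5p and miR-1915 were 3.32 and 2.62, against 4.03 and 3.36 with it. The signals of miR-1246, miR-135a*, miR-188-5p and miR-134 were undetected on all 4 vehicle arrays and were at least 6.55-fold, 6.36-fold, 6.15-fold and 4.45-fold higher with CG-1521. The signal of miR-22, which targets the estrogen receptor gene ESR1, rose by 3.04 ± 0.55 under every scaling, and by 2.23 without vehicle replicate 2. For each of these miRNAs all 4 treated arrays lay above all 4 vehicle arrays. In all, 54 of 149 miRNAs were called, 46 higher and 8 lower, and 30 of them, all higher, were called in the same direction under the 5 other scalings. Of the 54, 18 of the higher ones were undetected with vehicle. The groups did not overlap for 54 of the 149 tested miRNAs. Chance gives 2.86% for a miRNA picked without regard to the groups. The detection filter let in miRNAs undetected with vehicle, so the chance level among those tested is not known. With normexp background correction the changes of miR-1246, miR-135a*, miR-188-5p, miR-134 and miR-663 were negative.

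The lower calls in SUM149 depended on the scaling. The signals of miR-15b, miR-200b, miR-107 and miR-125a-5p fell by 1.04 ± 0.15, 0.66 ± 0.18, 0.74 ± 0.14 and 1.84 ± 0.56, but in the authors' value table their changes were positive, and with all human miRNAs in the percentile those of miR-200b and miR-107 were too. Without vehicle replicate 2 the miR-125a-5p change was -1.01. The signal of miR-892b fell by 2.27 ± 0.74 (limma adjusted p = 0.0256), a call lost without vehicle replicate 1 (-1.66), CG-1521 replicate 3 (-2.15) or CG-1521 replicate 4 (-2.02), and called under 3 of the 5 other scalings. The higher and lower calls numbered 46 and 8 here, 36 and 3 with all human miRNAs, 34 and 15 with quantile normalization, 59 and 0 in the authors' table, 43 and 15 with the 59-miRNA percentile, and 38 and 28 with the median ratio. The median change of all tested miRNAs was 0.13 here and 0.57, 0.38, 1.46, 0.00 and -0.24 in that order. Without vehicle replicate 2 there were 75 calls, 55 higher and 20 lower. With normexp, SUM149 CG vs vehicle gave 2 calls.

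With CG-1521 in SUM190, the signals of miR-1202, miR-638, miR-1207-5p and miR-663 rose by log2 3.51 ± 0.44, 3.44 ± 0.33, 3.31 ± 0.57 and 3.23 ± 0.64 (SE, n = 4 and 4), under every scaling. The miR-923 signal, from an entry later withdrawn as a ribosomal RNA fragment, rose from 0.98 ± 0.42 (SD) to 4.86 ± 0.44, by 3.88 ± 0.30 (limma adjusted p = 1.55e-08). The signals of miR-575, miR-494, miR-630, miR-1246 and miR-135a* were undetected with vehicle and at least 8.44-fold, 7.88-fold, 6.72-fold, 5.80-fold and 3.39-fold higher with CG-1521. The named entries that were later traced to tRNA fragments fell under every scaling: miR-1274a by 1.50 ± 0.40, miR-1260 by 1.32 ± 0.21, miR-1274b by 1.17 ± 0.29 and miR-720 by 1.09 ± 0.20. They do not show a fall of such entries as a class. Outside the naming rule, miR-1280 changed by -0.33 ± 0.23 (limma adjusted p = 0.283), called under 3 of the 5 other scalings. The miR-1308 signal rose by 0.59 ± 0.21 (limma adjusted p = 0.0353), called under 1 of them and at -0.06 under another. The signals of miR-27b and miR-193a-5p fell by 0.86 ± 0.21 and 0.70 ± 0.17, called under 4 and 3 of the 5 other scalings. With normexp the changes of both and of miR-1274a were positive. In all, 37 of 107 miRNAs were called, 30 higher and 7 lower, of which 19 and 4 held under the 5 other scalings. The groups did not overlap for 34 of the 107 tested miRNAs, against 2.86% by chance without the detection filter, which let in miRNAs undetected with vehicle here too.

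The share of lower calls in SUM190 also moved with the scaling. Higher and lower calls numbered 20 and 7 with all human miRNAs, 21 and 37 with quantile normalization, 34 and 5 in the authors' table, 20 and 60 with the 59-miRNA percentile, and 23 and 31 with the median ratio. The median change of all tested miRNAs was 0.22 here and 0.03, -0.20, 0.38, -0.43 and -0.17 in that order. With the replicate number as a block there were 53 calls, 40 higher and 13 lower. With normexp background correction, SUM190 CG vs vehicle gave 7 calls.

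**Figure D2:**
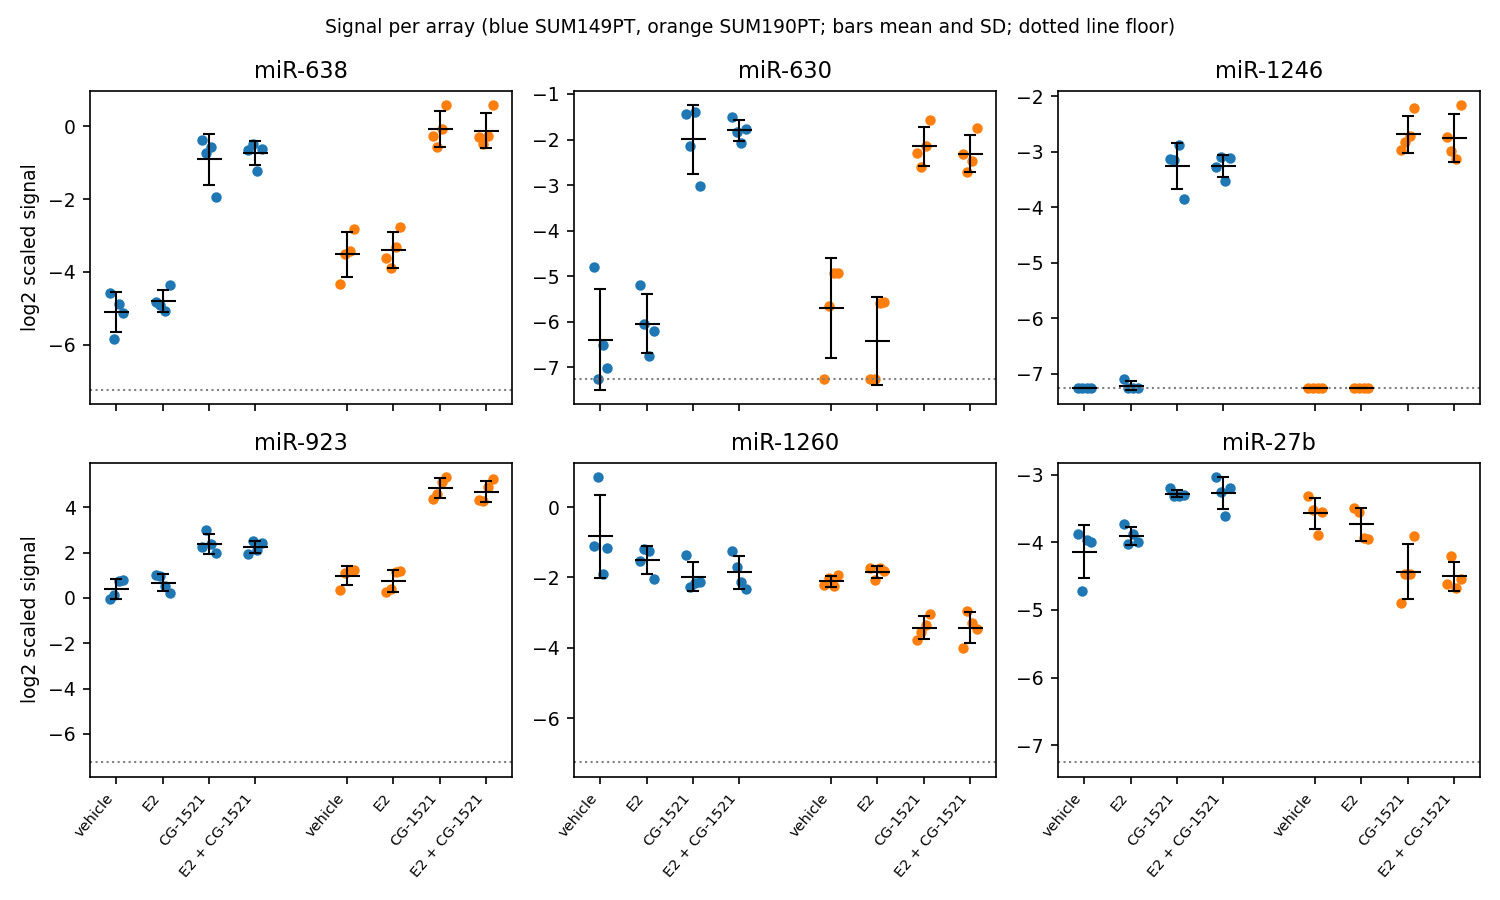
Log2 scaled signal of named miRNAs on each array of the 4 treatments in both lines; points are arrays, bars are group means with SD, and the dotted line is the floor of -7.25. The arrays with CG-1521 lie above the arrays without it for miR-638 and miR-1246 in both lines.

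Of the lists, the GC-rich high-numbered miRNAs had the largest number of members that rose with CG-1521, and also the most members tested. Over all miRNAs 46 of 149 rose in SUM149 and 30 of 107 in SUM190. Of 28 list members on the array, 0 in SUM149 and 9 in SUM190 were detected on every vehicle array. The other tested members passed the detection filter through a treated group, which favoured rises, so the counts, medians and camera p cannot be set against chance. In SUM149 12 of 20 tested members rose, also 12 adjusted over the list alone, with a median of log2 1.29, or 1.10 with members undetected in vehicle at their bound (camera adjusted p = 0.0414). In SUM190 13 of 16 rose, 14 adjusted over the list alone, with a median of 2.81, or 2.52 with bounds (camera adjusted p = 1.58e-05). With an estimated correlation neither was called (adjusted p = 0.932 with an estimated correlation in each line). Under the other scalings the list median stayed positive, at 0.94 to 2.88 in SUM149 and 2.08 to 2.76 in SUM190. On the same arrays the mean number of viral entries detected was 9.5 with CG-1521 against 4.75 with vehicle in SUM149, and 4.5 against 1.75 in SUM190, which did not pass the permutation test (exact adjusted p = 0.0857 for each).

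The miRNAs of 3 clusters with little signal in vehicle rose in part. The array holds 13 Xq27, 50 14q32 and 9 miR-302 and miR-371 members, and none was detected on every vehicle array in either line. Each tested member therefore passed the detection filter through a group with estradiol or CG-1521, which favoured rises. The counts and camera results of these clusters cannot be set against chance. From the Xq27 cluster, 3 of 3 tested members rose in SUM149: miR-513b by 2.56 ± 0.36, and miR-513c and miR-513a-5p at least 3.16-fold and 2.72-fold (camera adjusted p = 0.0414; adjusted p = 0.932 with an estimated correlation; adjusted p = 0.053 with the replicate block). From 14q32, 3 of 3 rose in SUM149 (miR-134, miR-494 by 2.87 ± 0.41, and miR-370 at least 1.05-fold; camera adjusted p = 0.0961) and 2 of 2 in SUM190 (miR-494 and miR-134, the latter at least 2.74-fold). The signal of miR-371-5p, the only member of its cluster tested in SUM149, rose by 2.28 ± 0.47. With normexp the changes of all 7 named members were negative in SUM149. Each count was the same adjusted over the list alone. None of the Xq27 and miR-371 cluster members was tested in SUM190, and no C19MC member in either line.

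Among entries later reassigned to other RNAs, 3 of 9 tested rose and 1 fell in SUM149 with CG-1521: miR-1246, miR-923 by 1.99 ± 0.28 and miR-1826 at least 1.63-fold, against miR-1274a, whose change of -0.98 ± 0.35 (limma adjusted p = 0.0419) was positive in the authors' table and not called without any 1 of 6 arrays (-0.83 to -0.98). In SUM190 3 of 8 rose, miR-1246 and miR-923 among them, and 4 fell. The scaling set of 19 miRNAs held 5 members of this list.

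Families of established function moved mostly in single members. Unless a second count is given, counts were the same adjusted over the list alone. In the miR-23/27/24 clusters, miR-27a, miR-27b and miR-23a rose in SUM149 by 1.17 ± 0.14, 0.86 ± 0.20 and 0.58 ± 0.14, and the other members of the 5 tested were not called. These 3 rises were called under 4, 3 and 0 of the 5 other scalings. In SUM190 miR-23a rose by 0.54 ± 0.15, called only in the authors' table among them, a change that was negative with quantile normalization and with the 59-miRNA percentile, and miR-27b fell. The signal of miR-29a rose by 0.65 ± 0.15 and 0.87 ± 0.14 in SUM149 and SUM190, 1 of 3 tested family members in each, but was called under only 2 of the 5 other scalings in each line and changed by 0.03 with quantile normalization in SUM190. In SUM149 1 of 3 tested members rose in the miR-30 family (miR-30a, 0.70 ± 0.15) and 1 of 2 in the cluster of miR-183, miR-96 and miR-182 (miR-183, 1.90 ± 0.46, and 1.24 without vehicle replicate 2), called under 2 and 4 of the other scalings. With normexp the SUM149 changes of miR-27b, miR-30a, miR-183 and miR-205 were negative. In SUM149 1 of 3 fell in the miR-15/16 family (miR-15b), 1 of 4 in miR-125/99/100 (miR-125a-5p) and 1 of 1 among p53-responsive miRNAs (miR-107), and each of these 3 changes was positive in the authors' table. None of the tested members of these lists was called in SUM190 (2, 2, 3, 1 and 2 tested) with the main scaling, but lower calls numbered 1, 0, 3, 1 and 1 with quantile normalization, 2, 2, 3, 1 and 2 with the 59-miRNA percentile, and 0, 0, 1, 1 and 1 with the median ratio. From miR-181, with no member tested in SUM149, miR-181a rose in SUM190 by 0.69 ± 0.20, 1 of 2 tested. Of the 5 other scalings only the authors' table called it, and the change was 0.04 with the 59-miRNA percentile.

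The miR-200 family, which represses ZEB1 and ZEB2, had 1 of 3 tested members lower in SUM149 (miR-200b, positive under 2 scalings) and 0 of 4 called in SUM190 by limma. In SUM190 3, 4 and 3 of the 4 were called lower with quantile normalization, the 59-miRNA percentile and the median ratio, and 1 higher in the authors' table. Of 4 tested epithelial miRNAs in SUM149, miR-205 rose by 0.79 ± 0.20, called under 2 of the 5 other scalings, and miR-200b fell, or 2 rose and 1 fell adjusted over the list alone. In SUM190 the 4 tested epithelial miRNAs were the 4 miR-200 family members above, with 0 called, and miR-205 was not tested. Of the ESR1-targeting miRNAs, miR-22 rose in both lines, by 1.09 ± 0.16 in SUM190, with 3 and 2 members tested. In SUM190 it changed by 0.21 and was not called with quantile normalization. The other SUM190 member, miR-193b, rose by 0.86 ± 0.32 (limma adjusted p = 0.0481) and lost its call without any 1 of 6 arrays (0.74 to 0.87) and under all other scalings but the authors' table. No let-7 member was called in 9 and 8 tested with the main scaling. Lower calls numbered 5, 8 and 4 in SUM190 with quantile normalization, the 59-miRNA percentile and the median ratio, and 3 in SUM149 with the median ratio. In miR-17-92 and its paralogs 0 of 8 were called in SUM149 and 1 of 7 in SUM190, miR-20b with -0.72 ± 0.27 (limma adjusted p = 0.047), which was not called adjusted over the list alone or without any 1 of 6 arrays (-0.61 to -0.71). With the 59-miRNA percentile 6 of the 7 were called lower. The p53 target miR-34a, tested only in SUM190, changed by 0.38 ± 0.16 (limma adjusted p = 0.0726). It was the only member of its family tested, so its call over that list alone rests on the unadjusted limma p of 0.0265. The miR-34a change was -0.38 with quantile normalization, -0.01 with the median ratio and, called lower, -0.27 with the 59-miRNA percentile. The change in miR-210, which responds to hypoxia, was 1.86 ± 0.70 in SUM149 (limma adjusted p = 0.0505), called in the authors' table. Its list holds 1 miRNA, so its call over the list alone was an unadjusted one. In SUM190 the miR-210 change was -0.18 ± 0.25, called lower with the 59-miRNA percentile. The single tested members of the miR-221 and miR-222 (miR-221, 0.31 ± 0.35), blood-cell (miR-223, -0.21 ± 0.80) and neuronal (miR-129-3p, -1.27 ± 0.62) lists in SUM149 were not called with the main scaling. The miR-223 change was called higher in the authors' table, and that of miR-129-3p lower with quantile normalization and the median ratio. No stromal, muscle or liver miRNA was tested in either line.

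**Figure D3:**
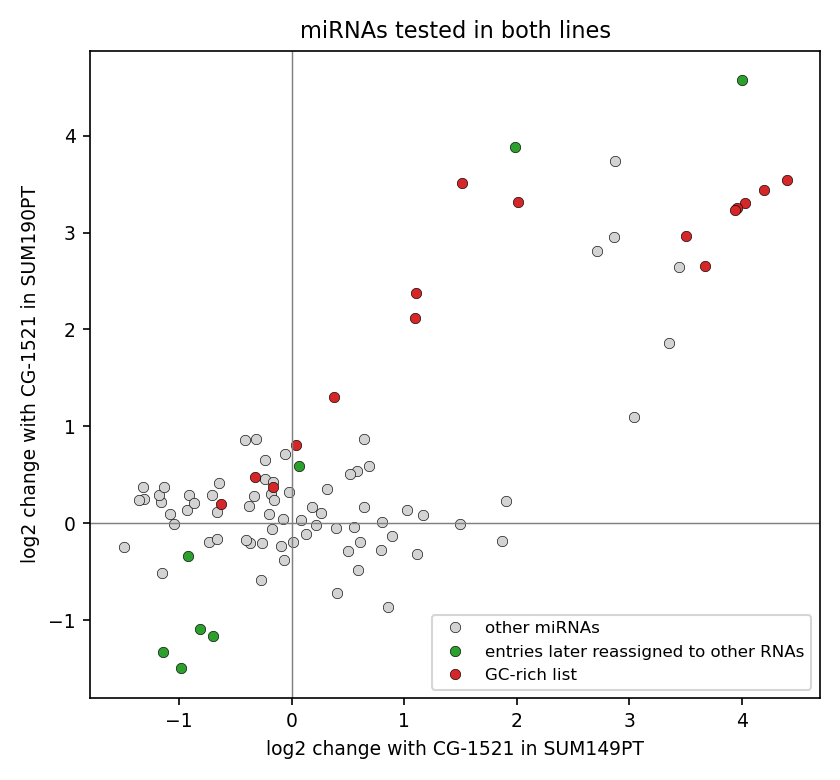
Log2 change with CG-1521 against vehicle in SUM149 (x axis) and in SUM190 (y axis) for the 96 miRNAs tested in both lines; each point is a miRNA, red for the GC-rich list and green for entries later reassigned to other RNAs. Red points reach log2 4.40 in SUM149 and 3.55 in SUM190.

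Among miRNAs tested in both lines, the CG-1521 rises were largely of the same miRNAs. Of the 46 higher calls in SUM149 and 30 in SUM190, those outside this set could not be compared. Of 96 miRNAs tested in both lines, 26 were called higher in SUM149 and 29 in SUM190, and 22 were shared, against 7.85 by chance (one-sided Fisher's exact p = 5.94e-12). They included miR-638, miR-1246, miR-630, miR-1207-5p, miR-663, miR-135a*, miR-923, miR-1202, miR-494, miR-134, miR-575, miR-22 and miR-29a. The detection filter let in miRNAs undetected with vehicle in both lines, miR-1246, miR-135a* and miR-134 among them. Such miRNAs entered through a treated group in each line, which favoured shared rises. The chance level among the miRNAs tested is therefore not known, and the Fisher's exact p for the rises cannot be taken at face value. Of 4 and 6 lower calls 1 was shared, miR-1274a, against 0.25 by chance (one-sided Fisher's exact p = 0.231), and 1 miRNA, miR-27b, was called in opposite directions. Across these miRNAs, which are not independent replicates, the changes correlated at r = 0.789 and rho = 0.465. The shared lower calls depended on the scaling. They numbered 4 with quantile normalization (2.67 by chance, Fisher's exact p = 0.251), 8 with the 59-miRNA percentile (4.33 by chance, Fisher's exact p = 0.00568) and 11 with the median ratio (5.63 by chance, Fisher's exact p = 0.0042). With the 59-miRNA percentile 4 miRNAs were called in opposite directions. Slide and CG-1521 coincided in both lines.

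The response to CG-1521 differed between the lines for 25 of 160 miRNAs, at different doses. The miR-27b response was lower in SUM190, with a difference of -1.72 ± 0.28 (SE, n = 4 per group; limma adjusted p = 5.08e-05). This tests the difference alone. The opposite directions rest on the calls within each line. For miR-877, miR-513c, miR-1469, miR-1826, miR-1290 and miR-513a-5p the differences were -2.93, -2.76, -2.10, -1.99, -1.70 and -1.64, with undetected values kept and floored. None of these miRNAs passed the detection filter in SUM190. The lowest signal detected on a CG-1521 array was log2 -6.13 to -4.51 in SUM190 and -7.25 to -6.09 in SUM149. A weaker response in SUM190 therefore cannot be told apart from a rise below detection there. Together with that of miR-27b these differences held under every scaling. With normexp all 7 differences were positive. The responses of miR-98, miR-22 and miR-183 were lower, with differences of -2.32 ± 0.40, -1.94 ± 0.58 and -1.67 ± 0.49, the latter pair at -1.13 and -1.01 without SUM149 vehicle replicate 2. They were called under 3, 4 and 3 of the 5 other scalings, and with normexp these differences were positive too. The miR-98 signal did not pass the detection filter in SUM190 either. The responses of miR-1202 and miR-923 were higher in SUM190 by 1.99 ± 0.58 and 1.90 ± 0.42. Those of miR-1275, miR-15b, miR-181a and miR-21 were higher by 1.28, 1.04, 0.75 and 0.70, and changed sign for miR-1275, miR-15b and miR-21 in the authors' table. Of the 5 other scalings 1 called those of miR-1202, miR-1275, miR-15b and miR-21, 2 that of miR-923 and 0 that of miR-181a. The miR-1275 call was lost without SUM149 CG-1521 replicate 4 (1.05) or SUM190 vehicle replicate 3 (1.09), and the miR-181a call without SUM190 vehicle replicate 2 (0.63). Of the 25, 6 were higher and 19 lower in SUM190, and 9, all lower, held under every scaling. The splits were 1 and 13 with all human miRNAs, 4 and 22 with quantile normalization, 0 and 32 in the authors' table, 1 and 34 with the 59-miRNA percentile, and 6 and 22 with the median ratio. The CG response SUM190 minus SUM149 gave 0 calls with normexp, 7 with the total gene signal and 5 among miRNAs detected on every array. Of 100 splits of the arrays 5, the real one included, gave 25 or more calls. Those splits left the CG-1521 response common to both lines in the values, so they could not decide on chance. With it removed, a step chosen after the results were seen, 1 of 100 splits, the real one, did.

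The combination of CG-1521 and estradiol against vehicle gave rises of the same kind. In SUM149 miR-630, miR-638, miR-663 and miR-1207-5p rose by log2 4.60 ± 0.50, 4.37 ± 0.35, 4.18 ± 0.34 and 4.17 ± 0.59 (SE, n = 4 and 4), and miR-1246 was at least 6.55-fold higher. In SUM190 miR-923, miR-1202 and miR-638 rose by 3.71 ± 0.30, 3.68 ± 0.44 and 3.40 ± 0.33, miR-1246 was at least 5.51-fold higher, and miR-1260, miR-27b and miR-720 fell by 1.32 ± 0.21, 0.93 ± 0.21 and 0.94 ± 0.20, each under every scaling. In SUM190 miR-148a also fell, by 0.70 ± 0.21, called under 4 of the 5 other scalings. With normexp the changes of miR-1260, miR-27b and miR-148a were positive in SUM190, and that of miR-1246 was negative in SUM149. Without SUM149 vehicle replicate 2 the miR-1207-5p rise was 3.47. The limma calls were 52 of 149 in SUM149, 45 higher and 7 lower, and 43 of 107 in SUM190, 35 higher and 8 lower. Of the GC-rich list 12 and 14 members rose, and 12 and 15 adjusted over the list alone (camera adjusted p = 0.0269 and 1.58e-05; adjusted p = 0.932 with an estimated correlation). The detection filter favoured rises of this list here too. The higher and lower calls were 36 and 2, 36 and 12, 34 and 0, 39 and 15, and 35 and 27 in SUM149 with all human miRNAs, quantile normalization, the authors' table, the 59-miRNA percentile and the median ratio. In SUM190 they were 21 and 8, 23 and 43, 36 and 9, 21 and 55, and 24 and 42. Normexp gave 2 calls for SUM149 E2_CG vs vehicle and 12 for SUM190 E2_CG vs vehicle.

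**Figure D4:**
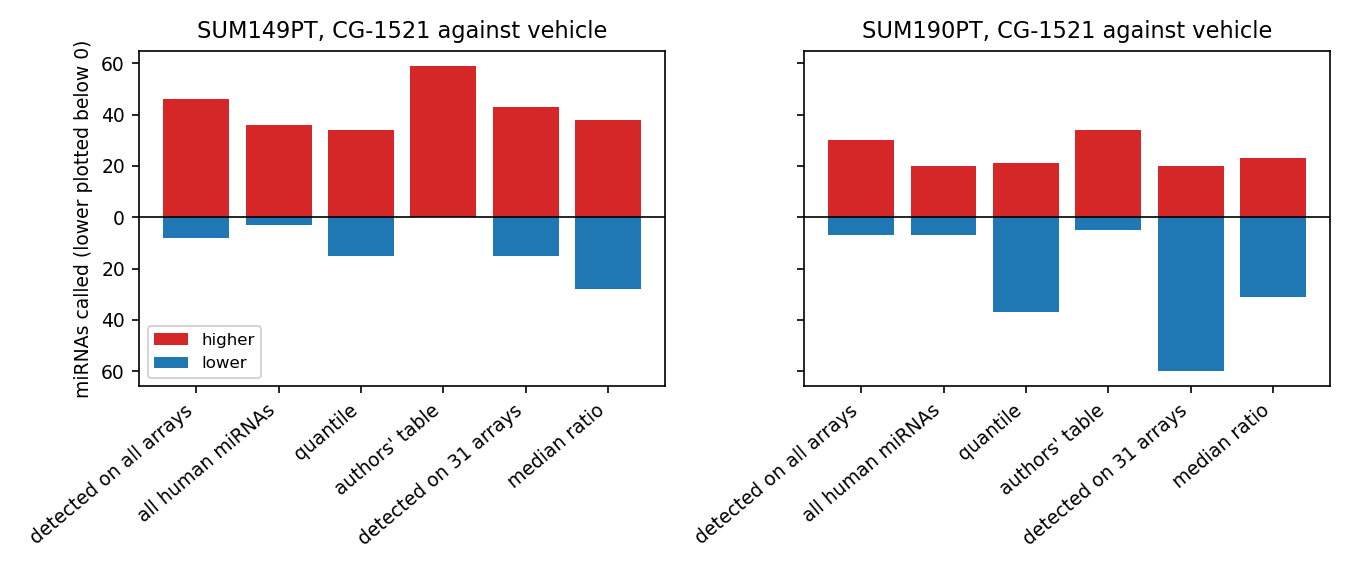
Number of miRNAs called higher and lower with CG-1521 against vehicle under 6 scalings in each line; bars above 0 are higher calls and bars below 0 lower calls. In SUM190 the lower calls range from 5 to 60.

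Estradiol changed no miRNA past the threshold in either line. Against vehicle limma called 0 of 149 in SUM149 (3 at an unadjusted p under 0.05, smallest adjusted p = 0.422) and 0 of 107 in SUM190 (5 at an unadjusted p under 0.05, smallest adjusted p = 0.662). Added to CG-1521 it gave 0 calls and 0 at an unadjusted p under 0.05 by limma in each line. The interaction with CG-1521 gave 0 calls and 0 at an unadjusted p under 0.05 by limma in each line. Averaged over both CG-1521 levels, the estradiol effect gave 0 limma calls in SUM149 and SUM190, with 0 and 6 at an unadjusted p under 0.05. The difference between the lines in the estradiol response gave 0 of 160 limma calls, with 17 at an unadjusted p under 0.05. The median SE of a change with estradiol was 0.39 in SUM149 and 0.23 in SUM190. This error was pooled over all groups of a line. In SUM149 the median SD was 0.84 in the vehicle group, which holds the dim replicate 2, against 0.33 with CG-1521 and 0.28 with the combination. In SUM190 the unpaired fit left the correlation between arrays of a shared number in the error. Counts of 0 lie below the share of 0.05 that chance gives, so they do not show that estradiol had no effect. In SUM190 the let-7 family ranked lower with estradiol as a set, with a median of -0.25 and 0 of 8 members called by limma (camera adjusted p = 0.0484), and lower again with estradiol added to CG-1521, with a median of -0.18 (camera adjusted p = 0.0159). Neither held with an estimated correlation (adjusted p = 0.932 with an estimated correlation). With the replicate block, estradiol gave 2 higher calls in SUM190 and 4 averaged over CG-1521, and the authors' table gave 23 and 17, all lower. The other scalings that gave calls in SUM190 pointed mostly the other way. The averaged effect had 4 higher and 0 lower calls with quantile normalization, 4 and 0 with the 59-miRNA percentile, and 4 and 2 with the median ratio. Estradiol against vehicle had 1 higher call with each of the latter pair.

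With vehicle, SUM190 had higher signals than SUM149 for miR-34a, miR-185, miR-148a, miR-29b-1*, miR-224, miR-181a and miR-200a*, which were undetected in SUM149 vehicle and at least 55.5-fold, 23.5-fold, 5.82-fold, 5.46-fold, 4.93-fold, 4.78-fold and 4.75-fold higher. The signals of miR-22, miR-99a and miR-183 were higher by log2 3.63 ± 0.41, 3.55 ± 0.30 and 3.33 ± 0.34 (SE, n = 4 and 4), and those of miR-22 and miR-183 by 2.81 and 2.67 without SUM149 vehicle replicate 2. The signals of miR-100 and miR-892b were undetected in SUM190 and at least 17.7-fold and 17.2-fold lower there, and miR-212 at least 2.15-fold. SUM190 was also lower in miR-1274a, miR-324-3p and miR-1274b, at -2.65 ± 0.40, -2.64 ± 0.22 and -2.58 ± 0.31, and in miR-17, miR-20a, miR-1260 and miR-24, at -1.80 ± 0.31, -1.28 ± 0.18, -1.28 ± 0.37 and -1.08 ± 0.15, with miR-1260 at -0.71 without that replicate. Those of miR-17, miR-20a and miR-24 were called under 3, 4 and 3 of the 5 other scalings. With normexp the differences of miR-17 and miR-212 were positive. With undetected values at the floor, the differences of miR-34a and miR-212 were 7.01 and -1.74 without that replicate, against 6.16 and -2.66 with it, and that of miR-892b was -3.63 without SUM149 vehicle replicate 1, against -4.23. Among families, let-7b, miR-200b, miR-200c and miR-141 were higher in SUM190 by 2.07 ± 0.17, 2.22 ± 0.16, 1.59 ± 0.30 and 0.98 ± 0.28. In all, limma called 81 of 160 miRNAs, 53 higher and 28 lower in SUM190, of which 19 and 21 held under the 5 other scalings. The splits were 32 and 29 with all human miRNAs, 51 and 33 with quantile normalization, 19 and 38 in the authors' table, 49 and 29 with the 59-miRNA percentile, and 36 and 49 with the median ratio. Line, medium and slide could not be told apart, and normexp gave 15 calls for SUM190 vs SUM149 vehicle.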

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

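The tests in this part on viral entries, array brightness, slide, array yield and the percentile among undetected entries were chosen after the results were seen, as was the regrouping with the common response removed. The comparison of the dim array with the other line and the other regroupings were set before their results.

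Of the GC-rich list 12 of 20 tested members in SUM149 and 13 of 16 in SUM190 were called higher with CG-1521 (adjusted p = 0.932 with an estimated correlation in each line), and 3 of 88 viral entries lay higher on all arrays with CG-1521 than on all without in both lines. All 20 in SUM149 passed the detection filter through a treated group, which favoured rises. The tables argue against array brightness as the whole cause: with signals divided by the control spots, the lowest list median with CG-1521 or the combination exceeded the highest with vehicle by log2 0.521 in SUM149 and 0.292 in SUM190, although in SUM190 these spots were brighter on every array with CG-1521 (means of 16118 with CG-1521 and 15385 with the combination against 10344; exact adjusted p = 0.0571 each, n = 4). With no scaling it did so by 1.20 and 0.64 on the treated arrays with a lower 75th percentile than the median vehicle array, 3 in each line. Other RNA on the probes may account for part of the rise, since the labels report no infection that would supply the 3 viral entries, hcmv-miR-UL70-3p, hsv1-miR-H1 and kshv-miR-K12-3, though in SUM190 the first was detected on 2 of 4 CG-1521 and 2 of 4 combination arrays and the second on 3 of 4 and 1 of 4. The slide cannot be told apart from CG-1521, because 0 slides held arrays with and without it, and an effect of CG-1521 on these miRNAs stays open as well.

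Viral entries detected on all 4 treated arrays, each of these above all vehicle arrays, were as follows. In SUM149 with CG-1521, hcmv-miR-UL70-3p, hsv1-miR-H1 and hiv1-miR-H1 were at least 5.34-fold, 2.63-fold and 1.42-fold higher, and kshv-miR-K12-3 was higher by log2 4.06. In SUM149 with the combination, hcmv-miR-UL70-3p and hsv1-miR-H1 were at least 5.76-fold and 2.61-fold higher, and kshv-miR-K12-3 and kshv-miR-K12-10b were higher by log2 4.16 and 1.82. In SUM190 kshv-miR-K12-3 was higher by log2 3.65 with CG-1521 and 3.67 with the combination, and kshv-miR-K12-10b was at least 1.08-fold and 1.66-fold higher. Entries detected on fewer treated arrays also lay above all vehicle arrays. In SUM190 these included hsv1-miR-H1, at least 2.60-fold and 2.34-fold higher, and hcmv-miR-UL70-3p, at least 2.22-fold and 2.27-fold higher. In SUM149 with the combination hiv1-miR-H1 was at least 1.23-fold higher.

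SUM149 vehicle replicate 2 stood apart from its group, with 59 detected miRNAs. Over the 59 miRNAs detected on the other 31 arrays it correlated at r = 0.748 with the other SUM149 vehicle arrays and at 0.546 with the SUM190 vehicle arrays, a difference of 0.201 that argues against a sample of the other line. The other SUM149 vehicle arrays correlated with each other at 0.987 or more. A lower labelling or hybridisation yield is a candidate explanation: the control spots stood at 0.147 and the 75th percentile at 0.128 of the mean of the group's other arrays, ratios that differ 1.15-fold. The files do not state what these control spots report, so a lower RNA input stays open as well, and no biological explanation was tested.

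With estradiol in SUM190, 23 miRNAs were called lower from the authors' values. Scaling to a percentile that lies among undetected entries is a candidate cause that the test could not single out. When the same signals were scaled on detected miRNAs, 0 of the 23 were left. The median change was then -0.12 and the median SE 0.247, against -0.51 and 0.262 before. That scaling also removes any dimming shared by all miRNAs, so it cannot tell the percentile from dimmer arrays. Without scaling the median change was -0.48, close to that in the authors' table. The estradiol arrays had a mean 75th percentile of 123 units against 158 with vehicle (exact adjusted p = 0.286). Their control spots had a mean of 7628 against 10344 (exact adjusted p = 0.0571). Dimmer arrays of the estradiol group remain open: without scaling 2 lower calls were made, fewer by far than 23, a drop that had been set beforehand as arguing against it. That bound was wrong, because it counted calls near the threshold: without scaling the 23 miRNAs kept a median change of -0.67 against -0.70 in the table, while putting only the unscaled changes or only the unscaled SE into the table already left 6 or 3 calls. An effect of estradiol itself was untested by these values.

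A single array stood apart from the other 3 of its group in 6 of 113 groups examined, where chance gives about 5%. Besides the array with 59 detected miRNAs, these were the following log2 scaled signals. The miR-1225-5p signal was -0.59 in SUM149 combination replicate 3, against -0.08 to 0.02. The miR-923 signal was 0.35 in SUM190 vehicle replicate 1, against 1.12 to 1.25. The miR-99a signal was -4.29 in SUM149 vehicle replicate 2, against -6.34 to -6.19, and the miR-17 signal was -3.05 there, against -1.76 to -1.60. The miR-20a signal was -2.09 in SUM190 vehicle replicate 3, against -1.79 to -1.78.

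The response to CG-1521 differed between the lines for 25 miRNAs by the test of the difference. The named differences above 0, SUM190 minus SUM149, were miR-1202 (1.99), miR-923 (1.90), miR-1275 (1.28), miR-15b (1.04), miR-181a (0.75) and miR-21 (0.70), in log2. Those below 0 were miR-877 (-2.93), miR-513c (-2.76), miR-98 (-2.32), miR-1469 (-2.10), miR-1826 (-1.99), miR-22 (-1.94), miR-27b (-1.72), miR-1290 (-1.70), miR-183 (-1.67) and miR-513a-5p (-1.64). Among these, miR-877, miR-513c, miR-98, miR-1469, miR-1826, miR-1290 and miR-513a-5p did not pass the detection filter in SUM190. For them a weaker response cannot be told apart from a rise below detection there. Regrouping the arrays as they were could not decide on chance. Of 100 splits 5, the real one included, gave 25 or more calls, and the highest of the others gave 41. This regrouping left the CG-1521 response common to both lines in the values. Splits that mix the groups unevenly could turn that response into a difference between the lines. A count as high as 41 can therefore arise without a structure of the samples. With the common CG-1521 response removed before regrouping, 1 of 100 splits, the real one, gave 25, and the highest other gave 8.

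For 5 comparisons 1 of 35 splits, the real one, gave as many calls, which argues against chance but does not exclude it. That share is the smallest that 35 splits allow, and it was not adjusted over the comparisons. In each of them the real split also followed the slides. CG-1521 gave 54 calls in SUM149 (highest other split 5) and 37 in SUM190 (highest other 8). The combination gave 52 in SUM149 (highest other 1) and 43 in SUM190 (highest other 3), and the vehicle arrays of the lines gave 81 (highest other 57). In SUM190, where the replicate numbers pair the arrays, the 7 other splits that part all 4 pairs gave at most 0 calls in these comparisons with vehicle and for estradiol, and the remaining splits put arrays of one number together. Splits that part all pairs are too few to settle the question in SUM190. Chance was not excluded for the counts of 0, which all splits reach. These were 35 of 35 splits for estradiol against vehicle (highest other 5 in SUM149 and 9 in SUM190) and for estradiol added to CG-1521 (1 and 9). They were 100 of 100 splits for the interaction (1 and 29), the averaged estradiol effect (15 and 1) and the difference in the estradiol response (5). Splits with 29, 15 and 9 calls against 0 point to a structure of the samples or of the slides, as the shared replicate numbers of SUM190 also do. The number coincides with the column of the slide, so these cannot be told apart.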

How the results depend on the processing

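The scalings over the 59 miRNAs detected on the 31 arrays other than SUM149 vehicle replicate 2, alone or without that array, were added after the data were seen. Of the named miRNA values under settings other than leaving out an array, 1394 kept their direction and side of the threshold, 204 lost their call and 56 reversed. Of those without 1 array, 1059 kept both, 37 lost their call and 0 reversed. Of the values that answer a comparison, 186 under other settings and 167 without 1 array stayed on their side or within 1.5 times the count, while 39 moved and 2 reversed under other settings and 1 moved without 1 array. Signal over background limits the calls: 69.9% of human values lay at the floor.

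With normexp the calls fell to 2 (SUM149 CG vs vehicle), 2 (SUM149 E2_CG vs vehicle), 7 (SUM190 CG vs vehicle), 12 (SUM190 E2_CG vs vehicle), 15 (SUM190 vs SUM149 vehicle) and 0 (CG response SUM190 minus SUM149; limma). After it undetected miRNAs kept medians of 112 to 136 units, but 382 in SUM149 vehicle replicate 4, 539 in SUM190 CG-1521 replicate 1 and 840 in SUM190 combination replicate 1. In SUM149 vehicle replicate 2 the median was 136 against 212 for the 75th percentile of the scaling set. What caused the reversals was not tested. Reversed values in SUM149 with CG-1521 were miR-1246 -0.17, miR-135a* -0.38, miR-663 -0.0038, miR-188-5p -0.24, miR-134 -0.39, miR-27b -0.46, miR-30a -0.56, miR-183 -0.62, miR-205 -0.23, miR-494 -0.14, miR-370 -0.72, miR-513c -0.71, miR-513a-5p -0.58, miR-513b -0.57, miR-371-5p -0.59 and miR-1826 -0.71. With the combination they were miR-1246 -0.0264, miR-135a* -0.21, miR-188-5p -0.00882 and miR-134 -0.22. In SUM190 with CG-1521 they were miR-1274a 0.0184, miR-27b 0.10, miR-193a-5p 0.0947 and miR-20b 0.11, and with the combination miR-1260 0.0222, miR-1274a 0.13, miR-27b 0.19, miR-148a 0.18 and miR-193a-5p 0.21. Between the vehicle arrays they were miR-212 0.48 and miR-17 0.0836. In the CG-1521 response difference they were miR-877 0.85, miR-513c 0.89, miR-98 0.92, miR-1469 0.84, miR-1826 0.89, miR-22 0.14, miR-27b 0.55, miR-1290 0.87, miR-183 0.77 and miR-513a-5p 0.78.

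The cause was not tested for the other settings either, except where fewer miRNAs were tested. In the authors' table these reversed in SUM149 with CG-1521: miR-15b 0.48, miR-200b 0.85, miR-125a-5p 0.0136, miR-107 1.02 and miR-1274a 0.51. So did miR-15b 0.23 with the combination, and in the response difference miR-1275 -0.26, miR-15b -0.40 and miR-21 -0.76. It gave 34 calls for SUM149 E2_CG vs vehicle, 23 for SUM190 E2 vs vehicle and 17 for the SUM190 averaged estradiol effect. With all human miRNAs in the percentile, miR-200b 0.043 and miR-107 0.0489 reversed in SUM149 and miR-21 -0.27 in the response difference, which had 14 calls. With quantile normalization, miR-23a -0.00793 reversed in SUM190 and miR-15b -0.11 in the response difference. It gave 58 calls for SUM190 CG vs vehicle, 66 for SUM190 E2_CG vs vehicle, 4 for the averaged estradiol effect and 4 shared lower calls. With the 59-miRNA percentile, miR-23a -0.11 reversed in SUM190, and the calls were 80 for SUM190 CG vs vehicle, 76 for SUM190 E2_CG vs vehicle, 1 for SUM190 E2 vs vehicle, 4 for the averaged estradiol effect and 8 shared lower calls. With the median ratio they were 66 for SUM190 E2_CG vs vehicle, 1 for SUM190 E2 vs vehicle, 6 for the averaged estradiol effect and 11 shared lower calls. Without SUM149 vehicle replicate 2 and with that percentile they were 82 for SUM149 CG vs vehicle and 51 for the response difference.

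With the total gene signal the calls were 32 for SUM149 CG vs vehicle, 1 for SUM190 E2 vs vehicle, 1 for the averaged estradiol effect and 7 for the response difference. With the replicate block they were 2 for SUM190 E2 vs vehicle and 4 for the averaged estradiol effect. Without a detection filter SUM190 E2_CG vs vehicle had 28. Among only the miRNAs detected on every array of the fit, fewer being tested, the calls were 4 and 4 of 29 in SUM149 (CG and E2_CG), 20 and 20 of 69 in SUM190, 14 of 19 between the lines and 5 of 19 for the response difference. With an estimated correlation 0 of 8 camera list calls were left. With the median over all human miRNAs in place of the 75th percentile, the difference in unscaled brightness from vehicle in SUM190 was 0.0311 units with estradiol and 0.0266 with the combination, against -34.9 and -2.93, and no test passed in either case. Leaving out 1 array gave 48 to 75 calls for SUM149 CG vs vehicle, 43 to 73 for SUM149 E2_CG vs vehicle, 32 to 42 for SUM190 CG vs vehicle, 32 to 47 for SUM190 E2_CG vs vehicle, 78 to 90 between the lines, 24 to 34 for the response difference, and 0 to 2 for the SUM190 averaged estradiol effect, 2 without CG-1521 replicate 4.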

Other observations

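The test of the clusters below was chosen after the result was seen. Beyond the comparisons, lists of other cell types left little signal. In both lines all 9 stromal, 6 muscle and 1 liver miRNAs were detected on no array. Of 8 blood-cell miRNAs 6 were undetected on every SUM149 array and 8 on every SUM190 array, and of 9 neuronal miRNAs 8 and 9. The imprinted 14q32 cluster was undetected for 41 of 50 members in SUM149 and 48 of 50 in SUM190, and the C19MC cluster for 36 and 37 of 39. All 4 miR-181 family members were undetected on every SUM149 array, against 2 of 4 in SUM190. All 9 let-7 members were detected on some SUM149 array, and 8 of 9 on every SUM190 vehicle array.

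The entry hiv1-miR-TAR-3p stood out in the other direction among the viral entries. In SUM149 it was detected on 3 of 4 vehicle arrays, at a log2 scaled signal of -2.34 ± 0.29 (SD, n = 4), and its change was -3.60 with CG-1521 and -3.88 with the combination. It was at the floor on all vehicle arrays of SUM190.

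One hypothesis was that CG-1521 may turn on miRNA clusters that are silent in these cells as a whole. The values argue against it: of 111 members of the 14q32, C19MC, Xq27 and miR-371 cluster lists, 7 were detected on all 4 CG-1521 arrays in SUM149 and 2 in SUM190. On all vehicle arrays 0 were detected in either line, and on any vehicle array 8 and 0.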
